A study of Homo sapiens with 24 samples.

How the data were processed

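RNA from 24 lung tumours labelled as squamous cell carcinoma was hybridised to Agilent human expression arrays in 1 colour (Cy3), with 1 array per tumour. The tumours form 1 group and carry the numbers of their labels, which run from 1 to 43 with gaps. No normal lung, treatment or other contrast was among the samples used here, so the measurement is the spread between tumours and what varies together. The labels do not state whether each tumour came from a different person. The p-values of relations and of limma fits therefore measure the spread between these samples. Those against random lists, of neighbouring genes and of comparisons between sets of genes rest on genes. They do not measure the spread between tumours.

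The deposited values were read as log2 values that the authors had centred per probe. The scale and the centring were found from the values, because neither is given in the sources used here. Every probe had a median of 0 over the 24 arrays (largest absolute median 5e-07), values lay on both sides of 0, and the widest range of a probe was 16.4 units, beyond what a scanner gives if the logarithm were natural or to base 10. The direction, higher for more RNA, was taken as usual for 1-colour intensities and is also not given in the sources used here. Scanner values were not used here, so log base and direction rest on these properties alone. Signals were extracted with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes. Background handling and any normalization between arrays are not given in the sources used here. Because each probe was centred, no probe's level can be set against that of another, no fold over a background can be given, and all values below are differences from the median tumour. The precision is limited by the number of arrays.

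The array medians over all probes were 0.20, 0.09, 0.14, 0.13, 0.15, 0.20, 0.08, -0.05 and -0.01 for tumours 1, 2, 3, 4, 5, 6, 7, 8 and 9. They were 0.01, -0.06, 0.20 and -0.01 for tumours 19, 20, 21 and 22, and -0.06, -0.12, -0.15, -0.12, -0.04 and -0.05 for tumours 25, 26, 27, 28, 29 and 30. For tumours 31, 32, 33, 35 and 43 they were -0.17, 0.30, -0.05, -0.14 and -0.10. The 75th percentiles of the arrays lay between 0.27 and 1.12 and the interquartile ranges between 0.75 and 1.53.

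The table held 41000 probes and 91 control probes, with 0 missing values. Of the 41000 probes, 29341 had 1 gene symbol in the platform annotation, 33 had several and 11626 had none. Probes with several symbols or none were not used. An Entrez identifier of the reference gene table was found for 29298 probes, and 0 symbols had to be updated. The order of genes along chromosomes, used for neighbouring genes only, is that of the RefSeq gene table of assembly GRCh38.p14. XIST, TSIX and all Y-linked genes were left out of every step. The 29260 probes used gave 18586 genes, of which 7594 had more than 1 probe. A gene's value is the mean of its probes. No filter on dim probes was applied. Probe sequences were not used here, so signal shared by near-identical copies was not separated.

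Array batches were sought among the control probes, since the labels give no slide or date. The median of 10 spike-in probes minus that of 12 background control probes parted the arrays into batch B (tumours 2, 3, 5, 6 and 7, mean -3.21 ± 0.33 SD, n = 5) and the rest. A control series probe pair then parted batch A (tumours 1, 4, 9, 19, 20 and 21, n = 6) from batch C (the other 13 arrays). Its difference ran from -4.42 to -0.95 in batch A and from -0.14 to 3.48 in batch C. Tumours 1 (-0.95) and 4 (-1.30) of batch A and 28 (-0.14) of batch C lay close to this cut, which is less clear than that of batch B. The thresholds of -2.5 and -0.5 were set after seeing these values, so the batches are a description of the arrays and not part of the design.

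The analyses, the 29 gene lists, a list of 22 single genes, the relations between lists and the rule for genes to name were fixed before the data were examined. The lists hold basal squamous, cornification, alveolar type II, airway secretory and ciliated markers, NRF2 targets, proliferation genes, T cell, cytotoxic, B and plasma cell, macrophage, neutrophil, MHC class II and interferon genes, and fibroblast and matrix, smooth muscle, endothelial, red blood cell and neuroendocrine genes. They also hold hypoxia and glycolysis, immediate early, heat shock, cancer-testis, checkpoint and aryl hydrocarbon receptor target genes and genes of the chromosome regions 3q26 to 3q29, 8p11, 11q13 and 7p11. Of the 423 distinct listed genes 397 were analysed, and the other 26 were not analysed here. Named were the 25 genes with the largest SD, in each list the 3 members with the highest and the 1 with the lowest correlation with the rest of the list, up to 10 genes per direction for each of 4 scores (adjusted p under 0.05 and the same sign without the 2 tumours of the most extreme score), all single genes, and both sides of each relation that names a gene. For the 10 per direction the order is by slope, a reading of the rule chosen after the data were seen. List members outside this rule that are named beside a small count were chosen after their values were seen.

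A gene's spread is its SD over 24 tumours, with a 95% interval from 2000 bootstrap resamples of tumours. A list's median SD was set against 10000 random lists of the same size (two-sided), and its mean pairwise Pearson r likewise (one-sided), each with Benjamini-Hochberg adjustment over 29 lists. Random lists were drawn from all genes and not matched on level, which the centring hides. A difference in level can therefore enter these comparisons. A list's score in a tumour is the mean of its members after scaling each to mean 0 and SD 1. Relations between scores were tested by two-sided permutation with 100000 resamples, for which 1e-05 is the smallest p they can give, by exact permutation within batch A, and again with batch as a block (batch means removed, permutation within batches). Each r was also computed without the 2 tumours farthest from the median of the first measure. Of 37 planned relations, 34 formed the tested family, 2 could not be computed because a partner gene was not analysed here, and 1 was set aside because its score fell into separate clusters. Every gene outside a list was fitted on that list's score with limma 3.58.1 (lmFit and eBayes) for 4 scores. The slope is the log2 change per SD of the score, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The score was also permuted 100 times. Fits within batches A and C were set against calls over all tumours, which include these arrays. Shared calls and signs are therefore no independent check. For the preset lists, counts adjusted over the list alone stand beside those over all genes.

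The alternatives planned were quantile normalization, an equal 75th percentile, the probe with the largest SD, leaving out the 25% of probes with the smallest SD, the median absolute deviation, Spearman correlation, 2 other scores, partial correlations and leaving out each tumour. Batch as a block, leaving out batch B and leaving out tumours 21 and 31 were added after seeing the data.

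The list tests were tested on simulated data. All lists sharing a factor of mean r 0.3 passed the coherence test (100%) and 0% of lists without one did. Of simulated pairs with r 0.7, 98.2% had p under 0.05. Of the first 500 pairs with r 0, 7.6% did, and of 5000 such pairs 5.4%. In the limma step, with 200 of 18586 genes following a simulated score, a slope of 1 was recovered for 81% of the changed genes with 8.47% of calls false, and a slope of 0.5 for 24% with 9.43% false. Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.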

Results

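Expression was measured in 24 lung squamous cell carcinomas, 1 array per tumour and n = 24 unless stated. The labels give a single group, so the question is how far these tumours differed in expression and which genes and gene groups varied together. All values are log2 differences from the median tumour of each probe.

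Cancer-testis antigens, which are usually silent outside the germline, were among the genes with the largest spread between tumours. MAGEA2B, one of them, had the largest SD of 18586 genes, 5.36 (95% interval 4.57 to 5.77), and spanned values from -3.80 to 10.02. MAGEA9 (SD 4.85), CTAG1A (4.58), MAGEA1 (4.21) and MAGEA12 (4.02) were also among the 25 most variable genes. The uroplakin UPK1B (4.35), the cornified envelope genes SPRR3 (4.06) and SPRR2G (3.85), the kallikrein KLK12 (4.05) and the defensin DEFB103B (4.03) were among these 25 as well. The surfactant and lung secretory genes SFTPB (3.98), SFTA3 (3.98), SFTPC (3.86) and DMBT1 (3.86) were as variable, as were the detoxification genes GSTA1 (4.12), GSTA5 (3.84) and UGT1A8 (3.84). The matrix metalloproteinases MMP13 (4.04) and MMP10 (3.94), the neuropeptide gene NTS (4.42) and the calcium-binding gene CALB1 (4.37) also ranked there, with LINC01206 (4.67), FETUB (4.01), C6orf15 (3.89) and CCDC190 (3.85). Over all genes the median SD was 0.81 (SE 0.03, bootstrap over tumours). An SD above 1 was found for 6324 genes (34.0%), above 2 for 777 and above 3 for 122. By median absolute deviation, 13 of the 25 genes stayed among the 25 most variable.

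**Figure D1:**
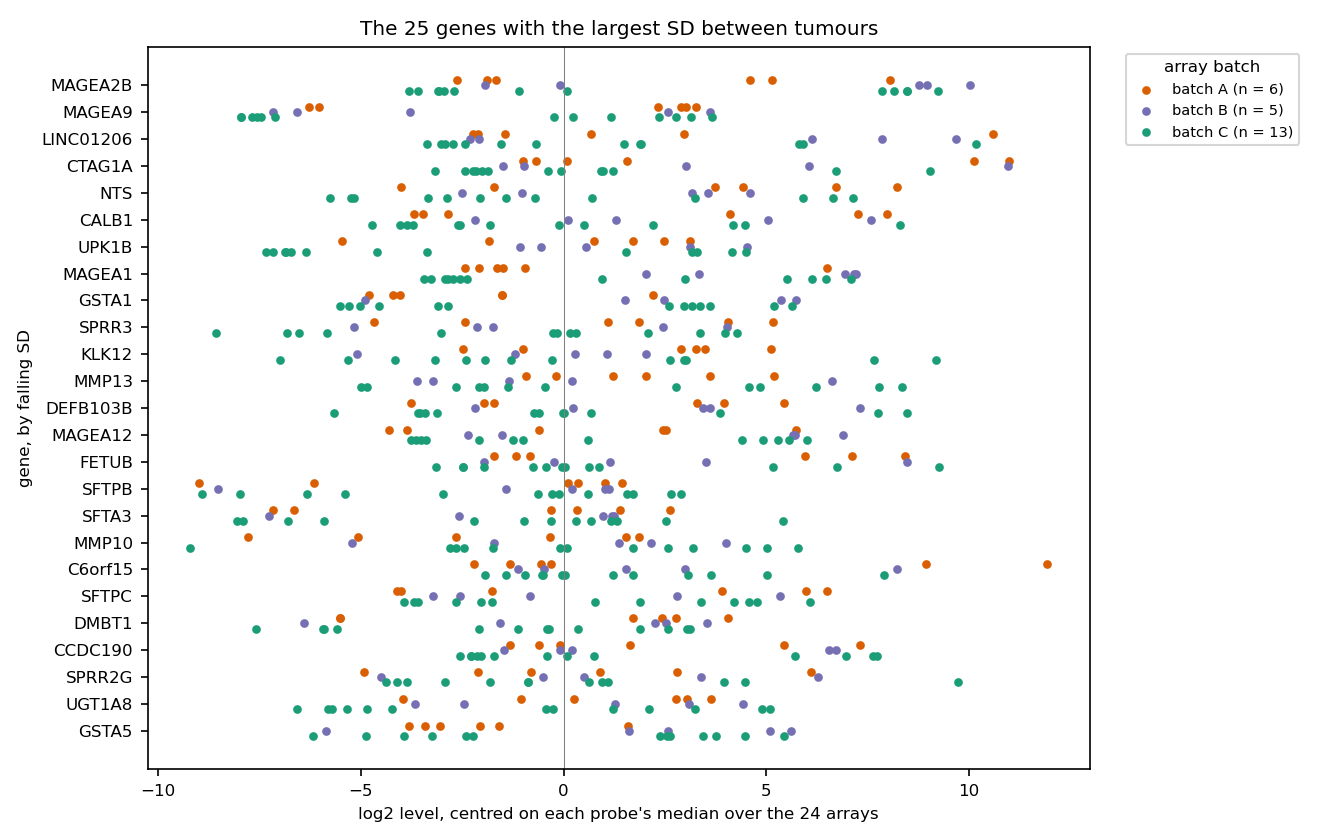
Log2 difference from the median tumour (horizontal axis) of the 25 genes with the largest SD, 1 point per tumour coloured by array batch, n = 24. MAGEA2B spans -3.80 to 10.02.

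Of the single genes often altered or targeted in squamous lung cancer, the cell cycle inhibitor CDKN2A varied most, with SD 2.93 (95% interval 2.29 to 3.30) and 8 tumours at least 2 below the median. FGFR3 followed with SD 2.24 and SOX2, a squamous lineage transcription factor, with SD 2.18 (1.69 to 2.57), where 7 tumours lay at least 2 above the median and 5 at least 2 below. CCND1 had SD 1.53, CD274 (PD-L1) 1.5, FGFR1 1.44, MTAP 1.37, EGFR 1.36, FGFR2 1.36, PDGFRA 1.14 and DDR2 1.08. FGFR1 lay at least 2 above the median in 5 tumours and at least 2 below it in 0. KEAP1 (0.86), NOTCH1 (0.85), RB1 (0.84), MYC (0.70), NFE2L2 (0.66), MET (0.63) and ERBB2 (0.57) varied less. Differences between the 3 array batches made up 65.7% of the variance of ERBB2, 50.3% of that of CD274, 44.1% of that of PDGFRA and 41.2% of that of DDR2.

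Among the preset groups, cornification genes, cancer-testis antigens and airway secretory markers had the largest median SD. Members of the cornification list, genes of the outer squamous layers, had a median SD of 3.25, against 0.81 for random lists of the same size, and a mean pairwise r of 0.566. SPRR1A (r = 0.922 with the rest of the list), SPRR2D (0.922) and SPRR1B (0.892) led it and KRT13 (0.443) was lowest. Basal squamous markers had a median SD of 2.31 and mean r of 0.589, led by the desmosomal cadherin DSG3 (0.945), TRIM29 (0.896) and KRT5 (0.847), with KRT14 lowest (0.482). Values ran from -11.19 to 2.43 for DSG3 and from -7.86 to 1.34 for TRIM29. For KRT5 they ran from -10.51 to 1.01 and for KRT14 from -8.38 to 2.68. These members thus reached further below the median tumour than above it. The score of this list was lowest in tumours 31 (-2.79) and 21 (-1.43). Airway secretory markers (median SD 2.61, mean r 0.518) were led by WFDC2 (0.835), PIGR (0.829) and BPIFB1 (0.826), while the mucin MUC5AC stood at 0.200. Alveolar type II markers (2.16, 0.530) were led by SFTPA1 (0.955), NAPSA (0.953) and SFTPD (0.938), and ETV5 stood apart at -0.233. Ciliated cell markers (1.57, 0.466) were led by ROPN1L (0.833), TEKT1 (0.826) and RSPH1 (0.784), with TPPP3 at 0.431. Cancer-testis antigens (3.00, 0.274) were led by MAGEA4 (0.794), CSAG1 (0.769) and MAGEA12 (0.761), with MAGEC1 at 0.157. NRF2 targets (1.82, 0.654), enzymes of the oxidative stress response, were led by AKR1C1 (0.919), SRXN1 (0.908) and CYP4F11 (0.905), with UGDH at 0.334.

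The most coherent lists were those of macrophage, fibroblast and matrix, MHC class II and T cell genes. Macrophage markers had the highest mean r of all lists, 0.834 (median SD 1.28), led by the complement genes C1QB (0.959), C1QA (0.950) and C1QC (0.949), with SIGLEC1 lowest at 0.748. Fibroblast and matrix genes had mean r 0.814 (median SD 1.42), led by COL3A1 (0.966), FAP (0.953) and COL1A2 (0.946), with LRRC15 lowest at 0.737. T cell markers (mean r 0.775, median SD 1.20) were led by CD2 (0.947), CD3G (0.942) and CD247 (0.937), with LCK at 0.628. MHC class II genes (0.795, 1.07) were led by HLA-DMA (0.946), HLA-DMB (0.937) and HLA-DPA1 (0.928), with their regulator CIITA at 0.759. Interferon-stimulated genes (0.690, 1.37) were led by IFIT1 (0.947), IFIT3 (0.931) and OAS2 (0.930), with RIGI at 0.575. Cytotoxic markers (0.645, 1.33) were led by GZMA (0.950), NKG7 (0.939) and GZMH (0.880), with EOMES at 0.350. Endothelial markers (0.585, 1.14) were led by TIE1 (0.957), CDH5 (0.949) and EMCN (0.932), with ERG at 0.381. B and plasma cell markers (0.573, 1.49) were led by MZB1 (0.946), TNFRSF17 (0.926) and CD79A (0.918), with PAX5 at -0.090. Checkpoint genes (0.415, 1.15) were led by ICOS (0.859), CTLA4 (0.836) and LAG3 (0.823), with FOXP3 at -0.038. Smooth muscle genes (0.378, 1.32) were led by LMOD1 (0.903), ACTA2 (0.882) and TAGLN (0.782), with DES at 0.195. Neutrophil markers (0.358, 1.26) were led by FPR1 (0.795), MMP25 (0.747) and MNDA (0.718), with MGAM at 0.094. Red blood cell transcripts (0.353, 1.47) were led by ALAS2 (0.843), HBB (0.842) and HBA2 (0.801), with AHSP at 0.057.

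Proliferation genes had a mean r of 0.592, led by BUB1 (0.911), CENPF (0.905) and CDK1 (0.887), with BIRC5 at 0.378. Their median SD of 0.77 lay below that of random lists, past the test only without the 25% of probes with the smallest SD (adjusted p = 0.0336). That setting removes genes by SD and so raises the SD of random lists, while the 0.77 stayed the same. Genes of chromosome region 8p11 had a mean r of 0.670 (median SD 1.14), led by DDHD2 (0.953), BRF2 (0.942) and NSD3 (0.932), with LETM2 at 0.456. Genes of 11q13 had 0.638 (1.12), led by PPFIA1 (0.916), FADD (0.904) and LTO1 (0.807), with CTTN at 0.544. Genes of 3q26 to 3q29 had 0.533 (0.71), led by ACTL6A (0.912), MRPL47 (0.908) and DCUN1D1 (0.903), with FNDC3B at -0.096. The 3 genes of 7p11 had 0.385 (0.64), EGFR with 0.573, LANCL2 with 0.522 and VOPP1 with 0.315. Hypoxia and glycolysis genes (0.498, 1.1) were led by PGK1 (0.874), VEGFA (0.802) and ADM (0.794), with COXFA4L2 at 0.480. Immediate early genes (0.472, 1.12) were led by FOS (0.908), ZFP36 (0.808) and NR4A1 (0.790), with KLF6 at 0.254. Heat shock genes (0.158, 0.71) were led by DNAJB1 (0.705), HSPH1 (0.468) and HSP90AA1 (0.419), with HSPA1A at -0.073. Neuroendocrine markers (0.077, 1.74) had SYP (0.482), SCG3 (0.362) and SCG2 (0.361) highest and GRP lowest at -0.429. Aryl hydrocarbon receptor targets (0.067, 0.92) had CYP1A1 (0.666), CYP1A2 (0.182) and AHRR (0.087) highest and CYP1B1 lowest at -0.130.

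The median SD lay above that of random lists, after adjustment over 29 lists, for 17 lists and below it for 0. The lists not past this test were proliferation, MHC class II, endothelial, hypoxia and glycolysis, immediate early, heat shock, checkpoint, aryl hydrocarbon receptor targets and the 4 chromosome regions. The T cell list was not past it with the probe of the largest SD (adjusted p = 0.0783), without the 25% of probes with the smallest SD (0.140), without batch B (0.0603) and without tumours 21 and 31 (0.0974). Macrophage, neutrophil and smooth muscle lists were not past it under the first 2 of these settings, and the cytotoxic list under the first. Leaving out probes by their SD raises the SD of random lists. The median SDs of the T cell, macrophage, neutrophil and smooth muscle lists did not change in that setting. Of the lists not past the SD test, 7 passed under another setting. Without the 25% of probes with the smallest SD, proliferation and 3q26 to 3q29 lay below random lists (adjusted p = 0.0336 for each), which that setting raises. The others lay above them. These were 8p11 (quantile normalization, an equal 75th percentile, batch means removed or without batch B), immediate early (quantile normalization, batch means removed, without batch B or by median absolute deviation), endothelial (the last 3 of these), hypoxia and glycolysis (the probe of the largest SD, batch means removed or median absolute deviation) and checkpoint (quantile normalization or median absolute deviation), with adjusted p of 0.0203 to 0.0467. Coherence passed for 27 of 29 lists, with an adjusted p of 0.000116 for all but heat shock genes (0.0112, and 0.057 without the 25% of probes with the smallest SD) and the 7p11 genes (0.0149). Behind the first of these lies 1e-04, the smallest p that 10000 random lists can give. It did not pass for neuroendocrine markers (adjusted p = 0.078) and aryl hydrocarbon receptor targets (adjusted p = 0.244). Of 384 members, 332 correlated positively with the rest of their list at a permutation p adjusted over the list alone, and 336 with adjustment over all members, on which GRP correlated negatively (r = -0.429, adjusted p = 0.0429). With batch means removed, 21 lists passed for SD and 27 for coherence, and FOXP3 stood at r = 0.424 with the other checkpoint genes. The score of 0 of 29 lists differed between batches after adjustment (3 at an unadjusted permutation p under 0.05: fibroblast and matrix, checkpoint and macrophage). The macrophage score averaged -0.82 in batch B (n = 5) and 0.35 in batch C (n = 13), and the fibroblast and matrix score -0.84 and 0.43.

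**Figure D2:**
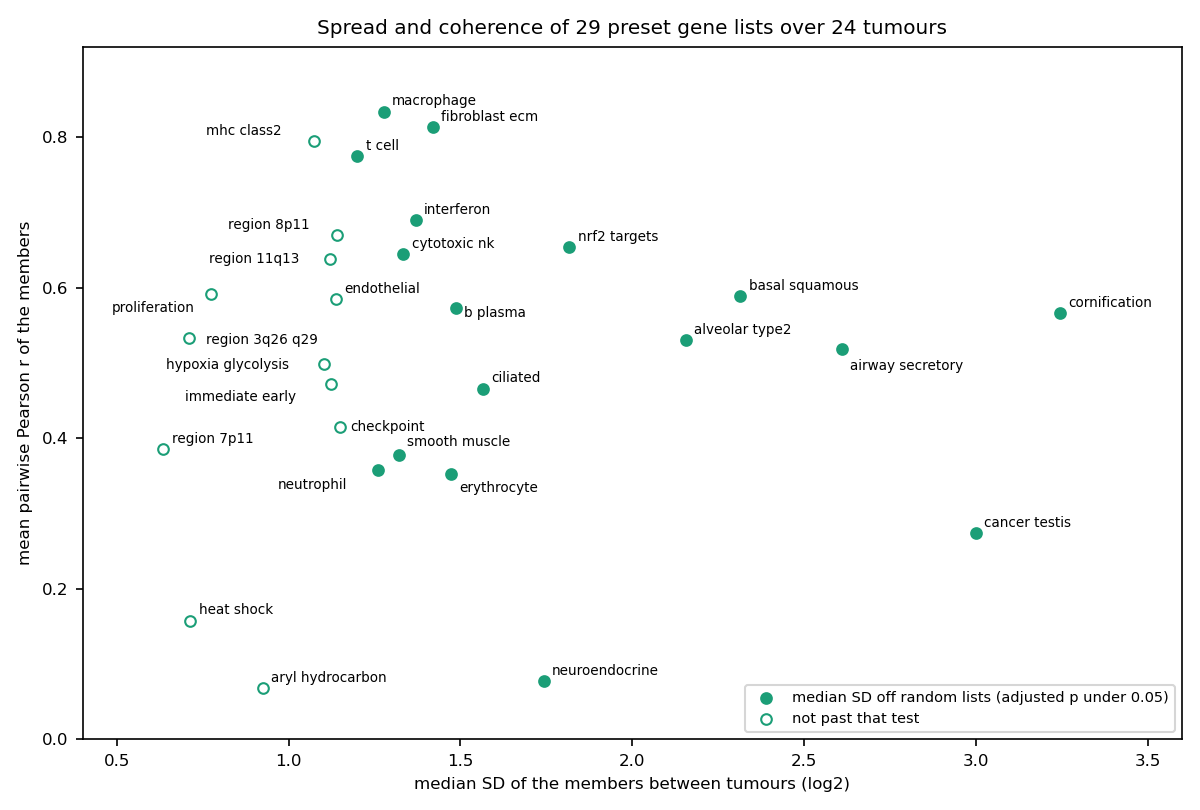
Median SD between tumours of the members of each of 29 lists (horizontal axis, log2) against the mean pairwise Pearson r of the members (vertical axis), 1 point per list. Filled points passed the test of SD against random lists. Cornification lies farthest right (3.25) and macrophage markers highest (0.834).

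SOX2 rose with the other genes of 3q26 to 3q29, the chromosome region that holds it. The correlation was r = 0.806 (permutation p = 1e-05, the smallest these permutations can give, adjusted p = 0.000113 over 34 relations) and rho = 0.829 (permutation p = 2e-05). It was 0.802 without the 2 tumours farthest from the median score, 0.795 with batch as a block, 0.841 within batch A (exact permutation p = 0.031) and 0.817 within batch C. FGFR1 rose with the other 8p11 genes (r = 0.545, permutation p = 0.00604, adjusted p = 0.0225, rho = 0.628, permutation p = 0.00127). This rested on tumours 9 and 30, without which r was 0.288. Leaving out tumour 9 alone (r = 0.455, adjusted p = 0.0775) or tumour 30 alone (r = 0.452, adjusted p = 0.0813) also ended the call. It was 0.540 with batch as a block (adjusted p = 0.052), 0.553 without batch B (adjusted p = 0.0573), 0.456 in batch A and 0.615 in batch C. For 11q13 the score fell into separate clusters: in 3 tumours above the gap CCND1 lay between 1.75 and 3.51, and in 21 below it between -2.66 and 1.32. Within those 21, r was 0.369 (permutation p = 0.10) and rho 0.284 (permutation p = 0.212), and r was 0.312 without the 2 farthest tumours. No relation was thus shown within the 21, while CCND1 did not overlap between the clusters. CDKN2A and its neighbour MTAP had r = 0.356 (permutation p = 0.0868, adjusted p = 0.178) and rho = 0.395 (permutation p = 0.0575). That r was 0.203 without the 2 farthest tumours, 0.138 with batch as a block, -0.802 in batch A and 0.110 in batch C, and it passed with quantile normalization (r = 0.538, adjusted p = 0.0261), with the interquartile range of the arrays held constant (0.553, adjusted p = 0.0185), without tumour 21 (0.541, adjusted p = 0.0251) and without tumours 21 and 31 (0.545, adjusted p = 0.0326).

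The NRF2 target score rose with KEAP1, the adaptor that marks NRF2 for degradation, and with NFE2L2, which encodes NRF2. For KEAP1, r was 0.826 (permutation p = 1e-05, adjusted p = 0.000113) and rho 0.763 (permutation p = 3e-05). It was 0.740 without the 2 farthest tumours, 0.776 with batch as a block, 0.446 in batch A (exact permutation p = 0.408) and 0.909 in batch C (permutation p = 1e-04). For NFE2L2, r was 0.537 (permutation p = 0.00661, adjusted p = 0.0225) and rho 0.569 (permutation p = 0.00422), and r was 0.542 without the 2 farthest tumours. With batch as a block it was 0.483 (adjusted p = 0.0579), with -0.028 in batch A (exact permutation p = 0.958) and 0.649 in batch C. Leaving out tumour 6 (r = 0.490, adjusted p = 0.0598) or tumour 8 (r = 0.482, adjusted p = 0.0577) ended the call. So did leaving out batch B (r = 0.460, adjusted p = 0.170) and holding the mean of the immune, stromal and vessel scores constant (r = 0.451, adjusted p = 0.0956). The 3q26 to 3q29 score and the NRF2 target score had r = 0.478 (permutation p = 0.0187, adjusted p = 0.0529) and rho = 0.557 (permutation p = 0.0055, adjusted p = 0.017), and r = 0.513 without the 2 farthest tumours. That r was 0.381 with batch as a block (adjusted p = 0.172), 0.324 in batch A and 0.538 in batch C, and it passed without tumour 4, 5, 8, 9, 20, 22 or 30, with r between 0.495 and 0.520. It also passed with the probe of the largest SD (r = 0.492, adjusted p = 0.0453), without the 25% of probes with the smallest SD (0.499, adjusted p = 0.0417), and with the mean of log2 values (0.508, adjusted p = 0.0361) or the median of members (0.527, adjusted p = 0.0252) as the score. Batch B, with 5 arrays, is too small for a value of its own in any relation. Batch B averaged 0.70 in the NRF2 target score against -0.17 in batch A and -0.19 in batch C.

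Lymphocyte groups rose together. The T cell score rose with the checkpoint genes (r = 0.831, permutation p = 1e-05, adjusted p = 0.000113, rho = 0.814, permutation p = 2e-05) and with the B and plasma cell genes (r = 0.779, permutation p = 2e-05, adjusted p = 0.000136, rho = 0.739, permutation p = 9e-05). It also rose with MHC class II genes (r = 0.624, permutation p = 0.00123, adjusted p = 0.00697, rho = 0.666, permutation p = 0.00055) and interferon-stimulated genes (r = 0.545, permutation p = 0.00598, adjusted p = 0.0225, rho = 0.580, permutation p = 0.00324). Without tumours 1 and 31, the 2 farthest, these were 0.768, 0.658, 0.609 and 0.570. With batch as a block they were 0.847, 0.775, 0.595 and 0.495, the last with adjusted p = 0.0637. Within batch A they were 0.848, 0.948, 0.582 and 0.805, and within batch C 0.808, 0.850, 0.584 and 0.280. Without batch B the MHC class II relation (r = 0.569, adjusted p = 0.0532) and the interferon relation (r = 0.446, adjusted p = 0.170) were not past the test, nor was the interferon relation without tumour 6 (r = 0.495, adjusted p = 0.0598). CD274 rose with the interferon score (r = 0.485, permutation p = 0.016, adjusted p = 0.0494, rho = 0.511, permutation p = 0.0112). This rested on tumours 6 and 26, without which r was 0.335, and was not past the test with batch as a block (r = 0.336, adjusted p = 0.296), with 0.583 in batch A and 0.267 in batch C. Leaving out any 1 of 17 tumours (1, 3, 4, 5, 6, 7, 9, 21, 25, 26, 27, 29, 30, 31, 32, 35 or 43) ended the call, with r between 0.400 without tumour 6 and 0.487 without tumour 32. So did leaving out batch B (0.320, adjusted p = 0.348) or tumours 21 and 31 (0.457, adjusted p = 0.0942) and holding the mean of the immune, stromal and vessel scores constant (0.314, adjusted p = 0.299). The T cell score and the macrophage score had r = 0.387 and rho = 0.386 (permutation p = 0.0625 and 0.064, adjusted p = 0.152 for r), with 0.428 without tumours 1 and 31, 0.363 with batch as a block, -0.303 in batch A and 0.425 in batch C. For the T cell score and the fibroblast and matrix score r was 0.119 and rho 0.124 (permutation p = 0.579 and 0.561, adjusted p = 0.703 for r), with 0.048, 0.058, 0.177 and -0.034 in the same order.

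Among epithelial groups, the alveolar type II score rose with the airway secretory score (r = 0.782, permutation p = 2e-05, adjusted p = 0.000136, rho = 0.769, permutation p = 3e-05, 0.762 without the 2 farthest tumours, 0.781 with batch as a block, 0.922 in batch A and 0.721 in batch C). Basal squamous markers rose with cornification (r = 0.589, permutation p = 0.00165, adjusted p = 0.00801, rho = 0.648, permutation p = 0.00095, 0.662 without the 2 farthest, 0.611 with batch as a block, 0.552 in batch A and 0.641 in batch C). The basal squamous score was not related to the alveolar type II score over all tumours (r = -0.097, permutation p = 0.674, rho = 0.252, permutation p = 0.234), but without tumours 21 and 31 r was 0.452 (permutation p = 0.0342), and without tumour 31 alone it was 0.211. With batch as a block it was -0.100, in batch A -0.041 and in batch C -0.198. It was not past the test with the T cell score either (r = -0.300, permutation p = 0.157, adjusted p = 0.242, rho = 0.052, permutation p = 0.809). That r was 0.232 without tumours 21 and 31, 0.076 without tumour 31, -0.287 with batch as a block, 0.233 in batch A (exact permutation p = 0.604) and -0.693 in batch C (permutation p = 0.016). Batch C holds tumour 31, which had the lowest basal squamous score (-2.79) and the highest T cell score (1.95). The batch C value was not tested without it. Also not past the test were 5 further relations. NRF2 targets with basal squamous markers had r = 0.236 and rho = 0.144 (permutation p = 0.277 and 0.501), with -0.010 without tumours 21 and 31, 0.194 with batch as a block, 0.156 in batch A and 0.299 in batch C. The 3q26 to 3q29 score with basal squamous markers had r = 0.357 and rho = 0.096 (permutation p = 0.0887 and 0.655), with 0.414, 0.329, 0.291 and 0.459 in the same order, here without tumours 3 and 9. That r was 0.186 without tumour 31, and -0.033 without tumours 21 and 31 with the scores made anew. NRF2 targets with T cell markers had r = -0.255 and rho = -0.130 (permutation p = 0.230 and 0.544), with -0.153, -0.167, -0.057 and -0.095, here without tumours 6 and 8. Proliferation with T cell markers had r = 0.046 and rho = 0.041 (permutation p = 0.831 and 0.850), with -0.125, 0.112, -0.775 and 0.439, here without tumours 22 and 29. Its sign turned without tumour 22 (-0.0038), 29 (-0.059), 31 (-0.011) or 33 (-0.025). Proliferation with fibroblast and matrix genes had r = -0.391 and rho = -0.330 (permutation p = 0.0592 and 0.113), with -0.285, -0.326, 0.160 and -0.557, and passed without tumour 19 (r = -0.509, adjusted p = 0.0396) or 22 (r = -0.491, adjusted p = 0.0474). In all, 11 of 34 relations passed the adjusted threshold, all 11 positive. With batch as a block 7 passed, all among these 11, and by Spearman 12 did. The 23 others lay between r = -0.391 for proliferation with fibroblast and matrix genes (adjusted p = 0.152) and 0.478, with adjusted p of 0.0529 to 0.929.

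**Figure D3:**
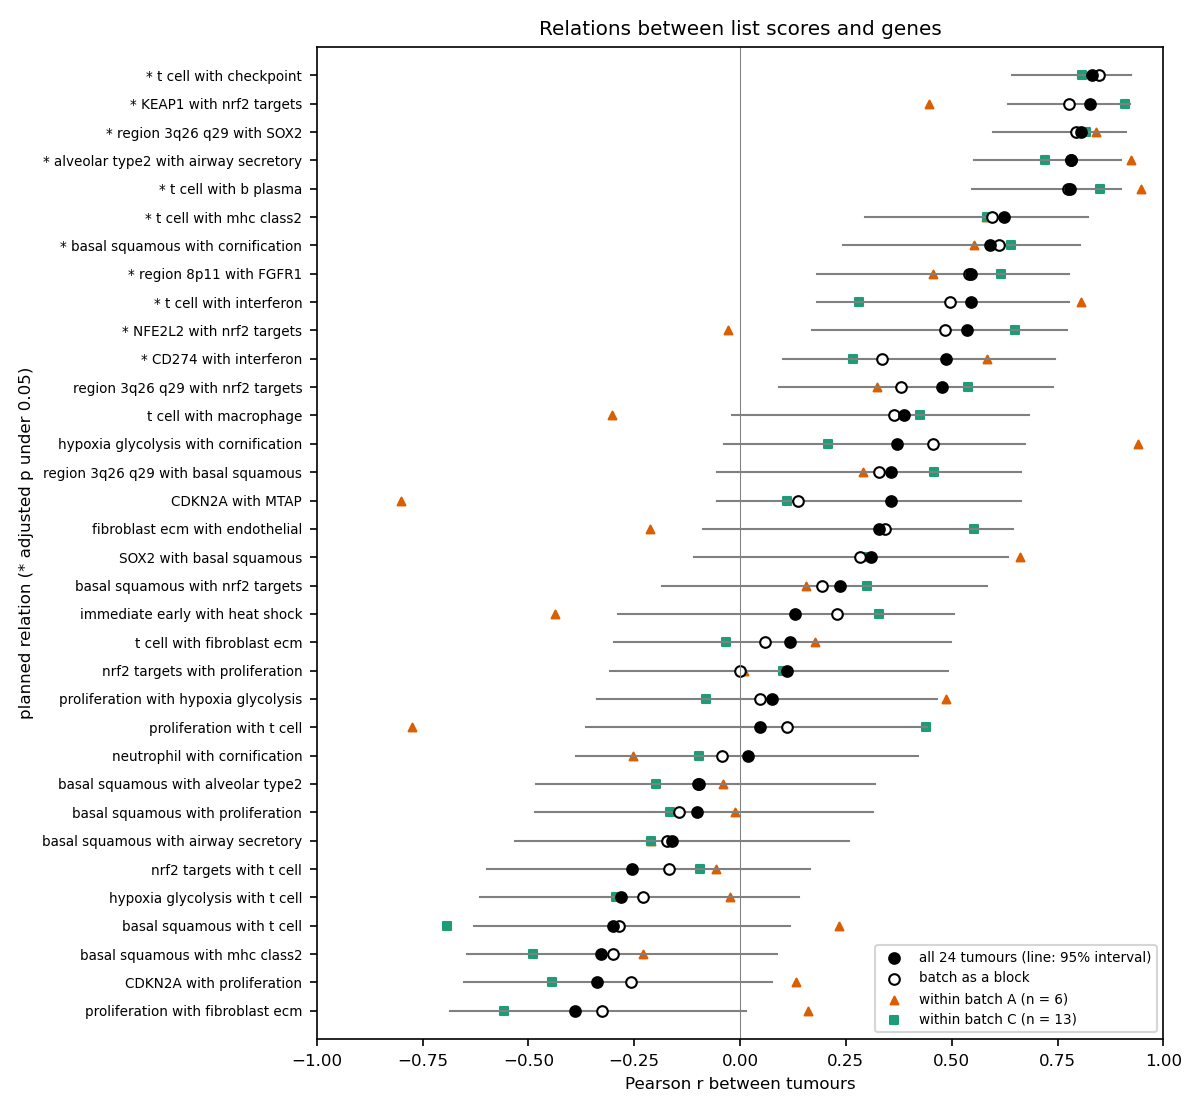
Pearson r over 24 tumours of the 34 relations tested (horizontal axis) with 95% intervals, beside the value with array batch as a block and the values within batches A and C. Relations past the adjusted threshold reach from CD274 with the interferon score (0.485) to the T cell score with checkpoint genes (0.831).

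Per SD of the NRF2 target score, the pseudogene NMRAL2P rose by 3.33 ± 0.35 (SE, limma adjusted p = 3.49e-06), the alcohol dehydrogenase ADH7 by 3.30 ± 0.34 (adjusted p = 2.71e-06) and the fatty acid hydroxylase CYP4F3 by 3.05 ± 0.22 (adjusted p = 4.03e-09). UGT1A8 (2.85), GSTA1 (2.69), UGT1A6 (2.67), GSTA5 (2.57), CYP4F12 (2.46), SOST (2.43) and FGFBP2 (2.36) followed. The vitamin D hydroxylase CYP24A1 (-1.62), the receptor MST1R (-1.36), SORCS2 (-1.30), EVA1A (-1.15), CRABP2 (-1.15), PON3 (-1.08), CCDC9B (-1.02), TRIM47 (-0.92), CXXC5 (-0.87) and the interferon regulator IRF7 (-0.76) fell. Of these 10, MST1R and PON3 alone were past the test with batch as a block, and the other 8 had adjusted p of 0.0654 (EVA1A) to 0.215 (CXXC5). Of the genes that rose, GSTA1 (adjusted p = 0.0857), GSTA5 (0.0634), SOST (0.0700) and FGFBP2 (0.0746) were not past it in that fit. Of 20 interferon-stimulated genes 1 fell over all genes (IFIH1, -0.69, adjusted p = 0.0266) and 17 fell adjusted over the list alone (median slope -0.70). In batch B the mean interferon score was -0.64 and the NRF2 target score 0.70. With batch as a block 6 interferon genes fell over the list alone (median slope -0.59), without batch B 0 (median -0.45, 4 at an unadjusted limma p under 0.05), with quantile normalization 7 (median -0.62), with an equal 75th percentile 10 (median -0.64), and without tumour 6, 8. SOX2 (1.40, adjusted p = 0.0451) was the 1 of 32 genes of 3q26 to 3q29 that rose over all genes, and 7 rose adjusted over the list alone, against 1 with batch as a block, 1 without batch B, 1 without tumour 28, 4 without tumour 29 or 31 and 3 without tumours 21 and 31. The contractile gene MYH11 (1.40, adjusted p = 0.0146) rose, alone among 10 smooth muscle genes on either adjustment, while the list's median slope was -0.07 (0.01 with quantile normalization, 0.08 with batch as a block, 0.24 without batch B). Without batch B 0 smooth muscle genes passed over the list alone, with 1 at an unadjusted limma p under 0.05. Of 6 genes of 11q13, CCND1 (-0.74), FADD (-0.50) and PPFIA1 (-0.63) fell adjusted over the list alone, against 0 with quantile normalization (3 at an unadjusted limma p under 0.05), 0 without batch B (2 unadjusted), 0 without tumour 7, 22 or 43 and 1 without tumour 28 or with an equal 75th percentile. The median slope of the 6 was -0.57, and -0.57, -0.58 and -0.54 with quantile normalization, without batch B and with an equal 75th percentile. On the same adjustment the heat shock genes DNAJB1 (0.53) and HSP90AA1 (0.34), the neuroendocrine genes UCHL1 (1.39) and SYP (0.68) and the aryl hydrocarbon receptor repressor AHRR (0.88) rose. Over all genes none of these 8 passed by limma, though all had an unadjusted p under 0.05. The heat shock count of 2 was 4 without tumour 2 or 8, 1 without tumour 3, 5, 6, 7, 21, 25, 27, 28 or 29, and 1 with batch as a block, without batch B, without tumours 21 and 31 or with quantile normalization. The neuroendocrine count of 2 was 1 with batch as a block and 1 without tumour 6, 22, 25, 27, 28, 29, 33 or 43, and the AHRR call was lost with quantile normalization and without batch B. In all, 119 genes rose and 30 fell among 18566, 149 calls against at most 3 in 100 permutations of the score. There were 69 calls with batch as a block, 31 within batch C (24 of them among the 149), 0 within batch A (n = 6, with 379 at an unadjusted limma p under 0.05, and the same sign of slope for 112 of the 149) and 30 without batch B. The 149 were picked on all tumours, these batches among them. Without tumours 6 and 8 there were 17 calls, 17 up and 0 down, and 61, 71 and 70 without tumours 6, 7 and 8 alone. Of the 20 named genes 7 (ADH7, CYP4F12, CYP4F3, MST1R, NMRAL2P, UGT1A6 and UGT1A8) kept the call with any 1 tumour left out, and 12 lost it without tumour 6. With an equal 75th percentile 109 rose and 8 fell.

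Cytotoxic and plasma cell genes rose with the T cell score. The immunoglobulin genes IGK (1.65 ± 0.27 SE per SD of the score, limma adjusted p = 0.000487) and IGHA1 (1.53), the B cell chemokine CXCL13 (1.51), the granzyme GZMA (1.45 ± 0.15, adjusted p = 6.21e-07), RGL4 (1.41 ± 0.13, adjusted p = 1.17e-07), JCHAIN (1.39), ZNF683 (1.33), IGLV1-44 (1.32), GZMK (1.31) and GNLY (1.30) had the largest slopes. The 9 genes that fell were IGF2BP2 (-0.90), KCTD15 (-0.60), DST (-0.59), SCHIP1 (-0.59), RNF217 (-0.57), CDAN1 (-0.48), ZFYVE9 (-0.46), TTBK2 (-0.42) and EIF2AK4 (-0.34). Of these, IGF2BP2 (adjusted p = 0.104), KCTD15 (0.0839) and DST (0.0972) were not past the test with batch as a block. Of 12 cytotoxic genes 10 rose over all genes and 12 adjusted over the list alone, and of 13 B and plasma cell genes 8 and 12. Of 9 checkpoint genes, 4 (CTLA4, ICOS, LAG3 and TIGIT) rose over all genes and 6 over the list alone. Of 8 MHC class II genes 0 and 8 rose, of 12 neutrophil genes 2 (MMP25 and VNN2) and 9, of 20 interferon genes 2 (IFI6 and OAS1) and 14, of 13 endothelial genes 1 (TEK) and 7, of 15 macrophage genes 0 and 2 (MS4A6A and SIGLEC1), and of 8 red blood cell genes 0 and 1 (HBD). Unadjusted limma p was under 0.05 for 8 of the MHC class II, 5 of the macrophage and 1 of the red blood cell genes. The interferon count over the list alone was 5 with batch as a block, 0 without batch B (6 unadjusted), and 6, 5, 7 and 5 without tumours 1, 6, 7 and 33. The neutrophil count was 5 without batch B or without tumours 21 and 31, and the endothelial count 4 with batch as a block or without batch B and 11 with an equal 75th percentile. The macrophage count was 0 with quantile normalization or batch as a block (5 unadjusted in each), 0 without batch B (2 unadjusted), 0 without tumours 21 and 31 (2 unadjusted), 5 with an equal 75th percentile, 4 with the interquartile range of the arrays as a covariate, 9 without tumour 1, 0 without tumour 4, 6, 7, 30 or 31 and 1 without tumour 33. The HBD call was lost with batch as a block, the probe of the largest SD or the interquartile range as a covariate, without batch B, without tumours 21 and 31 and without tumour 5, 7, 22, 26, 29, 30, 32 or 43. In all, 272 genes rose and 9 fell among 18572, against at most 9 calls in 100 permutations. With an equal 75th percentile 290 rose and 1 fell, without tumours 21 and 31 172 and 1, and without tumours 1 and 31 96 and 0. There were 263 calls with batch as a block, 82 within batch C (68 of them among the 281), 0 within batch A (n = 6, with 2176 at an unadjusted limma p under 0.05, and the same sign of slope for 280 of the 281) and 176 without tumour 31. The 281 were picked on all tumours, these batches among them. Of the 19 named genes 9 (GNLY, GZMA, GZMK, IGHA1, IGK, JCHAIN, RGL4, ZFYVE9 and ZNF683) kept the call with any 1 tumour left out, and 9 lost it without tumour 31.

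Among the genes that rose with the proliferation score were the kinesin KIF18B (1.01 ± 0.15 SE per SD, limma adjusted p = 0.000532), the kinases PBK (0.95) and HASPIN (0.91 ± 0.13, adjusted p = 0.000465), FAM83D (0.96) and the DNA repair gene XRCC2 (0.79). The largest slopes were those of the cancer-testis antigen PRAME (2.06, adjusted p = 0.0405), FABP7 (1.78) and the transcription factor MYB (1.43). SRSF12 (1.16) and MEX3A (0.80) also rose. The genes that fell with the largest slopes were the cartilage matrix gene COMP (-1.87 ± 0.39, adjusted p = 0.0149), NALF1 (-1.16), BMP2 (-1.06), WT1-AS (-1.02), SERINC2 (-0.98), the complement gene C3 (-0.96), RUNX2 (-0.96), CGB3 (-0.95), ADAM12 (-0.89) and PDGFB (-0.85). PRAME (adjusted p = 0.0769), MEX3A, NALF1, WT1-AS, RUNX2, CGB3 and ADAM12 were not past the test with batch as a block, the last 6 with adjusted p of 0.0573 (ADAM12) to 0.0871 (CGB3). Of 18 fibroblast and matrix genes 0 passed by limma on either adjustment, with 7 at an unadjusted p under 0.05 and a median slope of -0.47. Of 13 endothelial genes 1 (ROBO4, -0.72) fell over all genes and 3 (with PECAM1, -0.51, and TIE1, -0.63) adjusted over the list alone. That count was 1 with batch as a block, without batch B, without the 25% of probes with the smallest SD or with quantile normalization, 5 with the interquartile range of the arrays as a covariate and 0 with an equal 75th percentile (4 at an unadjusted limma p under 0.05). It was 1 without tumour 1, 2, 4, 6, 7, 8, 19, 20, 21, 25, 26, 27 or 32, 6 without tumour 22 or 35 and 5 without tumour 43. Of 32 genes of 3q26 to 3q29, 1 (ECT2, 0.75) rose on either adjustment, against 9 over the list alone with quantile normalization, 8 with an equal 75th percentile or the interquartile range of the arrays as a covariate, and 2 without tumour 31 or without tumours 21 and 31. Of 15 hypoxia genes 0 rose over all genes (2 at an unadjusted limma p under 0.05) and 1 (PDK1, 0.54) over the list alone. That count was 2 with quantile normalization, without batch B or without tumour 2 or 29, and 0 with batch as a block, an equal 75th percentile or the interquartile range as a covariate (2 unadjusted in each) and without tumour 4, 19, 20, 22, 25 or 33. In all, 141 genes rose and 50 fell among 18563, 191 calls against at most 4 in 100 permutations. With quantile normalization 219 rose and 14 fell, and with an equal 75th percentile 184 and 19. There were 213 calls with batch as a block and 105 without batch B. Within batch A there were 60 (27 up and 33 down), of which 1 was among the 191, and within batch C 52, of which 44 were. The slopes of all 191 had the same sign within batch A and within batch C as over all tumours. The 191 were picked on all tumours, these batches among them, so the shared sign is not a replication. Without tumours 22, 25, 29 and 33 there were 312, 118, 75 and 124, and without both 22 and 29 there were 67. Of the 20 named genes 8 (FABP7, FAM83D, HASPIN, KIF18B, PBK, SERINC2, SRSF12 and XRCC2) kept the call with any 1 tumour left out, and 11 lost it without tumour 29.

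With the basal squamous score the connexin GJB6 rose by 2.76 ± 0.33 (SE per SD, limma adjusted p = 8.03e-05), SPRR1B by 2.59, the protease TMPRSS11D by 2.55, KRT6C by 2.32 ± 0.32 (adjusted p = 0.000447), SERPINB13 by 2.13, LY6K by 2.00, DAPL1 by 1.99, KRT16P3 by 1.93, KRT16 by 1.92 and LGALS7B by 1.85. CALCA (-2.49), MYT1 (-1.89), FGL1 (-1.85), AQP6 (-1.74), ETNPPL (-1.67), PAEP (-1.55), TMEM229A (-1.48), KIF25-AS1 (-1.43), HGFAC (-1.26) and TBX10 (-1.20) fell. These 10 calls were all lost without tumour 31, whose score of -2.79 was the lowest, with slopes between -1.44 (CALCA) and -0.07 (TMEM229A). Without tumour 21, whose score of -1.43 was next, 4 of the 20 named genes lost the call. The slopes of TMEM229A (-1.70), KIF25-AS1 (-1.575) and TBX10 (-1.33) were then steeper. Without both tumours, slopes of the 10 lay between -0.46 (MYT1) and -0.02 (FGL1), with adjusted p of 0.806 (KIF25-AS1) to 0.995 (FGL1). Of all 20 named genes, GJB6 alone kept the call without tumour 31, and without both tumours KRT6C alone passed (slope 1.45, adjusted p = 0.0454). The other 9 genes that rose had slopes of 2.50 (SPRR1B, adjusted p = 0.0754), 2.22 (TMPRSS11D), 1.91 (KRT16P3), 1.74 (GJB6), 1.69 (SERPINB13), 1.49 (KRT16), 1.06 (LGALS7B), 0.90 (LY6K) and 0.73 (DAPL1) without both. Of the 20, TMEM229A alone was not past the test with batch as a block (adjusted p = 0.0505). Of 16 cornification genes 1 (SPRR1B) rose over all genes and 10 adjusted over the list alone, a count that was 12 without both tumours and 6 without tumour 5 or 22. The hypoxia-inducible COXFA4L2 (1.18) and the glucose transporter SLC2A1 (0.93) rose, 2 of 15 hypoxia genes over all genes and 3 over the list alone (with NDRG1, 0.70; 1 of 15, COXFA4L2, without tumours 21 and 31), and so did HSPB1 (0.54), 1 of 9 heat shock genes on either adjustment. Of the 11 neuroendocrine genes, CALCA fell on either adjustment, and over the list alone that call was lost without tumour 31. Adjusted over the list alone, AKR1B10 (2.15) of 20 NRF2 targets and EGFR (0.69) of 3 genes of 7p11 rose and LPCAT1 (-0.69) of 15 alveolar genes fell. Over all genes 0, 0 and 0 passed by limma, with 3, 1 and 1 at an unadjusted p under 0.05. These calls were lost without tumour 31, the EGFR and LPCAT1 calls also without tumour 21, the AKR1B10 call with quantile normalization, the EGFR call without batch B and the LPCAT1 call with the interquartile range of the arrays as a covariate. The alveolar median slope was -0.13, and 0.11 with quantile normalization. Without tumours 21 and 31 it was 0.84, and over the list alone SFTPA2 rose and LPCAT1 did not pass. In all, 66 genes rose and 36 fell among 18573, 102 calls against at most 37 in 100 permutations. There were 2 calls without tumour 31, 73 without tumour 21, 67 without tumour 43, 9 without tumours 21 and 31, 46 without batch B, 56 within batch C (36 of them among the 102), 0 within batch A (n = 6, with 951 at an unadjusted limma p under 0.05, and the same sign of slope for 100 of the 102), 5 by Spearman correlation and 17 with quantile normalization, of which 15 rose and 2 fell. With batch as a block there were 146. The 102 were picked on all tumours, batches A and C among them. Batch C holds tumour 31, and the fit within batch C was not repeated without that tumour.

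No array was a copy of another: the correlation over genes between 2 arrays was at most 0.453 (tumours 25 and 29), with a median of -0.027 over 276 pairs. The 19 pairs with consecutive numbers were more alike than the others (mean r 0.052 against -0.013, one-sided permutation p = 0.0331). The 5 arrays of batch B, all with numbers from 2 to 7, had a mean r of 0.295 with one another. Without them the difference was 0.010 (permutation p = 0.384). With batch means removed it was -0.069, but that step by itself lowers the r between arrays of a batch, so the sign cannot be read. Between the batches, 3385 genes (18.2% of 18586) differed by limma.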

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

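The settings chosen only after the data were seen are batch as a block or batch means removed, leaving out the 5 arrays of batch B and leaving out tumours 21 and 31, and all others were planned. Of the values that answer a comparison, 144 kept their direction and their side of the threshold under these settings, 12 counts moved by more than 1.5 times, 5 values turned direction and 1 was no longer past its test. Of the other values 2420 kept both, 91 moved, 46 came to pass their test, 263 no longer passed and 1 turned direction, the r of FOXP3 with the other checkpoint genes, -0.038 as deposited and 0.424 with batch means removed. Among these other values, those past the test under neither setting count as kept. With the settings that leave out each tumour included, 46 of them, in 19 results, changed sign. For relations and array likeness that answer a comparison, every change of sign counts as turned, whether or not the test was passed. The numbers kept in the 2 sets therefore cannot be compared.

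Genes with an SD above 1 ranged from 5305 to 8028 (6324 as deposited), lists more variable than random lists from 13 to 21 (17), and coherent lists from 25 to 27 (27). Relations past the test were 12 with quantile normalization and 11 with an equal 75th percentile (11 as deposited), 7 with batch as a block and 6 without batch B. The mean of the immune, stromal and vessel scores (T cell, macrophage, fibroblast and endothelial) was held constant for 22 relations, of which 5 passed against 7 as deposited. Without tumours 21 and 31, with every score made anew, r turned to 0.436 for basal squamous with alveolar type II, 0.210 for basal squamous with T cell and -0.033 for 3q26 to 3q29 with basal squamous. Proliferation with T cell turned to -0.040 with the interquartile range of the arrays held constant.

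Genes following the basal squamous score numbered 17 with quantile normalization, 49 with the interquartile range of the arrays as a covariate, 46 without batch B, 9 without tumours 21 and 31 and 5 by Spearman (102 as deposited). For the NRF2 target score they numbered 69 with batch as a block and 30 without batch B (149). For proliferation there were 114 without the 25% of probes with the smallest SD and 105 without batch B (191), and for T cell 173 without tumours 21 and 31 (281). The excess likeness of consecutive arrays, 0.065, was 0.00999 without batch B and -0.069 with batch means removed. Removing batch means by itself lowers the r between arrays of a batch. For the other changes the cause was not tested.

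With each tumour left out in turn, calls ranged from 2 to 113 for basal squamous, 61 to 214 for NRF2 targets, 75 to 312 for proliferation and 176 to 314 for T cell, and relations past the test from 8 to 13. The r ranged from -0.144 to 0.211 for basal squamous with alveolar type II, 0.118 to 0.316 with NRF2 targets and -0.431 to 0.076 with T cell. It ranged from -0.315 to -0.161 for NRF2 targets with T cell, -0.059 to 0.114 for proliferation with T cell, 0.783 to 0.833 for 3q26 to 3q29 with SOX2, 0.186 to 0.424 for 3q26 to 3q29 with basal squamous and 0.804 to 0.859 for T cell with checkpoint genes. Among these values 296 kept direction and side, 10 counts moved and 6 values turned, and of the others 2245 kept both, 10 came to pass and 265 no longer passed. The probe with the highest mean level and a filter on mean level were not run because every probe is centred, and the probe with the largest SD and the removal of the 25% with the smallest SD took their place. Precision is limited by the number of arrays, and signal over background was not analysed here.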

Other observations

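The tests chosen only after the result was seen are those of array batches for KEAP1, the 3 for pseudogenes (background shift, genomic DNA and abundant parent transcripts) and the other splits into batches. The tests of neighbouring genes and of regional dosage and tumour cell content for KEAP1 were set before their results were seen.

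Tumour 31 stood at the end of several scores at once. It had the lowest basal squamous score (-2.79, next -1.43 in tumour 21), the lowest 3q26 to 3q29 score (-1.15) and the lowest cancer-testis score (-0.92). Its alveolar type II (1.13), T cell (1.95), cytotoxic (1.91) and checkpoint (1.20) scores were the highest of the 24. Tumour 30 had the highest ciliated (2.59), airway secretory (1.58) and 8p11 (2.05) scores, and tumour 32 the highest macrophage (2.31), MHC class II (1.85), neutrophil (1.33) and hypoxia (1.39) scores. The array of tumour 32 also had the highest median (0.30) and 75th percentile (1.12) over all probes. Whether the ranks of tumour 32 depend on that was not tested. Tumour 29 joined the lowest proliferation score (-1.94) with the highest fibroblast and matrix score (2.16). The 3 tumours above the gap of the 11q13 score were 22 (2.16), 43 (2.10) and 33 (1.63).

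Genes that lie side by side on a chromosome varied together across the genome, not only in the 4 preset regions. In windows of 15 neighbouring genes reduced to 1 gene per name root, the highest mean pairwise r was 0.522 on chromosome 3 (UBXN7 to DLG1). Next came 0.508 on chromosome 8 (RAB11FIP1 to PLEKHA2, a window that holds NSD3 and FGFR1), 0.491 on chromosome 19 (GNG7 to GNA11), 0.466 on chromosome 1 (PPIE to EXO5, which holds MYCL) and 0.427 on chromosome 9 (RPP25L to ATOSB). The share of such windows past the test ran from 91.9% on chromosome 14 (34 of 37) to 47.4% on chromosome 15 (18 of 38).

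That breadth is the first pattern weighed. With all genes kept, 934 of 1179 windows (79.2%) had a mean r above random gene sets after adjustment, against 0 with gene positions shuffled. Related neighbouring genes and array batches are argued against as the whole source, since 848 windows passed with 1 gene per name root and 972 with batch means removed. Scores of windows 5 places apart correlated at 0.380, and those on different chromosomes at 0.0463, an excess of 0.334 (permutation p = 0.000999, the smallest that 1000 random orders can give). Gains and losses of long chromosome segments may be the source, a hypothesis that these values fit but that stays open, because DNA copy number was not analysed here and a design with 1 group gives no biological contrast to test.

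The second is KEAP1, whose product marks NRF2 for degradation and which nonetheless rose with the NRF2 target score, ranking 7 by correlation among 18566 genes outside the list. Array batches are argued against as the whole source by r = 0.776 with batch as a block, though within batch A r was 0.446. Dosage of the region is argued against by its 20 nearest genes, whose median r with the score was 0.113 (quartiles -0.273 to 0.245). With the mean of the T cell, macrophage, fibroblast and endothelial scores held constant, r was 0.802 (permutation p = 2e-05). Variation of that mean is thereby argued against as the whole source. The scores in it were only loosely related (T cell with fibroblast and matrix r = 0.119, T cell with macrophage 0.387). Each was not held constant by itself, so the share of any single one of these cell types stays open. Normal airway and alveolar epithelium is not part of that mean, so the share of tumour cells itself stays open. A response of KEAP1 to NRF2 activity may remain as a hypothesis, which was not tested.

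The third lies on the 5 arrays of batch B, where 194 genes lay above all 19 other arrays and 37 below, against at most 5 above in 100 random sets of 5 arrays. Of the 194, 140 were protein-coding (0.831% of 16838), 42 were pseudogenes (7.64% of 550) and 9 of the protein-coding genes were histone genes (12.3% of 73, with a median shift of 0.71), against 1.04% of all genes, and the largest shifts were those of the pseudogenes NACA4P (6.65), EEF1DP4 (5.44) and TPT1P8 (5.16) and the protein-coding PABPC3 (6.27) and ANO8 (5.39), chosen after their values were seen. A shift of dim probes was present, with medians of 0.83 for olfactory receptor genes, 0.63 for background probes, 0.45 for pseudogenes and 0.06 for all genes. Of the olfactory receptor genes 0.893% (1 of 112) were among the 194, a lower share than that of pseudogenes (Fisher's exact p = 0.00516). Background probes averaged 0.47 in batch B, 0.51 in batch A and -0.50 in batch C, so their shift was against batch C and not batch A. In tumours 1 (0.93) and 21 (1.15) of batch A they lay above every array of batch B (highest 0.73, tumour 6). A probe that only followed background could hence hardly lie above all 19 other arrays. The low share of olfactory receptor genes was thus largely set beforehand and by itself decides nothing. Background alone is argued against for the 42 pseudogenes because they did lie above all 19. Genomic DNA stays open, since the median shift beyond background probes was 0.20 for olfactory receptor genes (95% interval 0.10 to 0.37) and -0.19 for all pseudogenes, which decides nothing. Signal from abundant parent transcripts on shared probes may contribute to the pseudogene part, as ribosomal protein pseudogenes shifted by 0.72 more than other pseudogenes (20 against 530, permutation p = 0.0031), but the histone genes and why batches would differ stay open and no biological contrast was tested.

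Between batches A, B and C, 3385 genes differed by limma, and of 100 splits into groups of these sizes 1, the real one, gave as many. The highest of the others gave 4, so a random grouping is argued against for this count. The batches were cut from control probes of these same arrays after their values were seen. Random splits do not test a grouping chosen in that way.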
